A study of Mus musculus with 6 samples.

How the data were processed

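The series compared airway smooth muscle cells cultured from tracheal explants of mice that overexpress the beta2-adrenergic receptor with cells of nontransgenic mice. Per the labels, RNA was taken at passages 8 to 10 from cultures started in medium with 20% serum, and over 90% of such cells were smooth muscle cells by staining for smooth muscle actin. Each of the 6 samples is 1 two-colour array on which transgenic and nontransgenic RNA, labelled with Cy5 and Cy3, competed for the same printed probes. Transgenic RNA carried Cy5 on 4 arrays (1A, 1B, 2A and 2B) and Cy3 on 2 arrays (1C and 2C). The labels do not say what the numbers 1 and 2 or the letters A to C stand for; the arrays that share a number are called a set here. Each array was counted as 1 replicate. Nothing in the labels says that arrays of 1 set came from separate cultures or animals, so p-values measure the spread between arrays, which may be technical.

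The deposited table holds 1 log2 ratio per probe and array. Per the labels' protocols, RNA was reverse transcribed and hybridised competitively to prepared slides; the scanner, background correction, normalization, filters and the direction of the ratio are not given in the sources used here. The deposited log2 values have array medians of 0.0, 0.0, 0.0007, 0.0005, -0.0012 and 0.0001 for arrays 1A, 1B, 2A, 2B, 1C and 2C. The values of each array were thus already centred, by a step that is not given. The lowest value equals the log2 of a ratio of 0.01 and stands for a floor; 63 probes of array 1C lay there, 10 of array 2C, 8 of 1B, 6 of 1A, 2 of 2B and 0 of 2A. Spot intensities were not used here, so the signal behind a ratio is unknown and only the number of arrays can be given as a measure of precision.

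The sign of the swapped columns was examined before any fit. Of 47 probes beyond 2-fold with the same sign on the 4 arrays with transgenic RNA in Cy5, 40 kept that sign on both swapped arrays, 6 had the opposite sign on both and 1 was mixed. All 32 positive probes of this group kept their sign, and of the 15 negative ones 8 did. Equal signs are what columns already turned to 1 direction give, but a dye bias of single probes gives them in columns that were not turned. A constant dye bias cancels in the difference of set 2 minus set 1, and that difference correlated with r = 0.183 between the orientations over 7855 probes within 4-fold on every array; the positive sign favours turned columns, but it is weak, and a dye bias that varies between sets could give it too. The swapped columns were taken as already turned, and no sign was changed. If they were not turned, the genes called for the transgene here carry a dye bias, and the term called dye holds the transgenic effect. Whether the common direction is transgenic over nontransgenic is not settled by the labels. It is likely transgenic over nontransgenic, because channel 1 of the 4 arrays in the majority orientation is Cy5 and holds the transgenic RNA and because the transgenic cells are the test condition of the design. Against this, the titles of those 4 arrays name the nontransgenic RNA first, which read as a ratio would give the reverse. If the ratio is the reverse, every "higher" below reads "lower" and every sign turns.

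The table lists 8734 probes. The platform annotation gives 1 gene symbol for 7540 of them, several for 14 and none for 1180; 7493 probes matched a gene of the GRCm38.p6 gene table through the Entrez ID, and 0 symbols had to be updated. No coordinates are given, because the annotation names no genome build. Probes of 1 symbol were averaged on each array, and probes with several symbols or none stayed separate under their probe number. A row entered the fit with values on at least 4 arrays and both dye orientations, which left 6807 rows, 5644 of them with 1 symbol. Over 1356 genes with at least 2 probes, the fitted log2 ratios of the first 2 probes correlated across genes with r = 0.315, and the highest of 200 shuffles gave 0.09; genes are not independent replicates. Of 93 called genes with at least 2 probes, 91 had all probes on the same side. The calls rest on the mean of these same probes, so this is no separate test of their agreement.

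The model was limma (version 3.58.1, R 4.3.3): lmFit and eBayes with a transgenic coefficient and a dye coefficient over all 6 arrays, and Benjamini-Hochberg adjusted p under 0.05. The dye term is needed because 4 to 2 orientations do not cancel a dye effect. The same fit gave the dye comparison, and a further term gave the difference of set 2 minus set 1. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 26 lists that had at least 5 measured genes; camera with an estimated correlation, fry and Fisher's exact test on the number of called genes stand beside it. Alternatives with blocks, weights or robust variances used cameraPR on the moderated statistics. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Groups, lists, tests, the named-gene rule and the alternatives named first below were fixed before the data were examined. Named are Pln, the 15 genes with the largest higher and the 15 with the largest lower ratio among 1-symbol genes past the threshold with the same sign on every array, up to 4 genes with the smallest p of each list, 3 for the dye effect and 5 for the set difference. Outside this rule, and after the results were seen, the text names the remaining called genes of the cell cycle and matrix lists (Mcm2, Mcm4, Col5a2, Thbs2 and Lox), the fibroblast-expressed Dpt, Pdgfra and Col1a1, and genes of the closing observations.

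The alternatives left out the dye term, used only the 4 arrays with transgenic RNA in Cy5, treated the set as a random or fixed replicate block or as the replicate itself, centred or scaled the arrays, changed the filter on missing values, tested each probe on its own, used robust variances or array weights, moved the threshold and left out each array in turn. Alternatives chosen after seeing the data set floor values to missing, dropped sparsely measured probes before averaging, or used 1 set alone. Averaging has a known side effect here: for Suox and Megf9 a second probe had values on 2 arrays only, at the floor on 1C and 2C for Suox and on 2C for Megf9, so the averaged ratio mixes different probes on different arrays.

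The fit was tested on simulated ratios for 6807 rows with 200 changed genes. With independent arrays of equal noise it recovered 49.3% of genes changed by 0.5 on the log2 scale, 83.6% of those changed by 1 and 100% of those changed by 2, and 6.1% of its calls were false. With the unequal noise of the real arrays 9% were false, and with an added correlation of 0.3 within a set 22.3% were false. In that last simulation the random block gave 12% false calls. With independent arrays the block gave more false calls than the main fit, 9.5% with equal and 15.1% with unequal noise. In the simulation with correlated sets, the set means with n = 2 gave 0% false calls and recovered 55.4% of genes changed by 2.

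The arrays differed in spread over probes, which holds real change as well as noise. The array weights that limma estimated from the fit were 0.42 for both 1C and 2C. They were 0.55 for 1A, 0.56 for 1B, 3.7 for 2A and 5.01 for 2B. The SD of the log2 ratios over probes was 0.569 for array 1A, 0.608 for 1B, 0.499 for 2A, 0.516 for 2B, 1.04 for 1C and 0.467 for 2C, and 16% of the probes of array 1C lay beyond 2-fold against 2.97% of those of 2C.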

Results

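The data are 6 two-colour arrays, each of which set RNA of airway smooth muscle cells that overexpress the beta2-adrenergic receptor directly against RNA of nontransgenic cells. The receptor couples to the stimulatory G protein and raises cyclic AMP, and airway smooth muscle is the cell layer that relaxes in response to inhaled beta-agonists. The design asks how lasting activity of the receptor alters gene expression. Arrays 1A, 1B and 1C form set 1 and arrays 2A, 2B and 2C set 2; transgenic RNA carried Cy5 on 4 arrays and Cy3 on 1C and 2C. Between 8495 and 8555 of the 8734 probes had a value on each array. Ratios are log2 and likely transgenic over nontransgenic, on the basis given with the processing; the signs mirror if the ratio is the reverse. All results take the swapped columns as already turned to this direction, which the labels do not state; if they were not, the genes called for the transgene carry a dye bias instead. Errors are the standard errors of the limma fit over n = 6 arrays, and adjusted p-values are limma's with Benjamini-Hochberg adjustment unless another test is named.

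Transgenic cells had higher ratios for Thy1, a surface glycoprotein, for C1s1 and C1ra, the proteases that start the classical complement pathway, and for Cst3, the cysteine protease inhibitor cystatin C. They had lower ratios for Ccnd1, the cyclin that drives entry into the cell cycle, for Col3a1, a fibrillar collagen, and for Gsta4, a glutathione transferase. Thy1 reached 2.73 ± 0.21 (6.62-fold, adjusted p = 0.00411, higher on 6 of 6 arrays), and Ccnd1 reached -1.29 ± 0.10 (2.45-fold lower, adjusted p = 0.00411, lower on 6 of 6 arrays). In all, 484 of 6807 rows passed the threshold, 274 higher and 210 lower; 416 of these carried 1 gene symbol, 233 higher and 183 lower. The median size was 0.60 for the higher and -0.52 for the lower rows, and 42 higher and 28 lower rows lay beyond 2-fold.

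Among the 15 largest higher genes, the complement proteases stood at 3.03 ± 0.65 for C1s1 (adjusted p = 0.0485) and 2.01 ± 0.175 for C1ra (adjusted p = 0.00438). Array 1A set the size of C1s1: its ratio there was 6.93 against 2.12 to 2.72 on the other 5 arrays, and without 1A the fit gave 2.50. Cpxm1, a carboxypeptidase-like secreted protein, was at 2.27 ± 0.205 and Ly6c1, a surface antigen, at 2.07 ± 0.22. Cst3 (1.71 ± 0.20), Rasl11a, a Ras-like GTPase (1.67 ± 0.125), Pamr1 (1.64 ± 0.17), Dkk3, a secreted Dickkopf family protein (1.63 ± 0.14) and Mamdc2 (1.62 ± 0.33) followed. Fhl1, a LIM domain protein of muscle, was at 1.60 ± 0.08 with 1.45 to 1.90 on single arrays, the narrowest relative spread of this group. Aldh1a7, an aldehyde dehydrogenase, was at 1.58 ± 0.27 and Tnc, the matrix protein tenascin C, at 1.57 ± 0.14. The transcripts 9030619P08Rik (2.17 ± 0.39) and 4933427D14Rik (1.38 ± 0.15) complete the group. Adjusted p-values of the 15 genes ran from 0.00172 for Fhl1 to 0.0485 for C1s1. C1s1 lost the call without 1B, without 2A and without 2B, at adjusted p from 0.0922 to 0.105. Mamdc2 lost it without the same arrays, at 0.0567 to 0.111. The transcript 9030619P08Rik lost it without 1A, without 1B and without 2A, and Aldh1a7 without 2A and without 2B. Without array 1C, C1s1, 9030619P08Rik, Cst3, Mamdc2 and Aldh1a7 lost the call, with Cst3 at 1.52.

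Among the 15 largest lower genes, Gzmf, a granzyme, stood at -2.09 ± 0.21 and Gsta4 at -1.94 ± 0.15. LTO1 (-1.68 ± 0.15), Tm4sf1, a membrane protein (-1.46 ± 0.16), Map2, a microtubule-associated protein (-1.42 ± 0.21), and Pdgfc, a platelet-derived growth factor (-1.42 ± 0.10), came next. The semaphorin receptors Plxnd1 (-1.39 ± 0.20) and Nrp2 (-1.13 ± 0.14) both fell. Col3a1 was at -1.29 ± 0.10, with -1.25 and -1.33 at its separate probes. Smim3 was at -1.25 ± 0.19, Abcg2, an efflux transporter, at -1.25 ± 0.15, Pmepa1 at -1.22 ± 0.11 and Slc5a3, the sodium-coupled inositol transporter, at -1.15 ± 0.08. Megf9 also met the rule at -1.95 ± 0.12 on 5 arrays, but its ratio rests on a second probe at the floor on array 2C; with floor values set to missing it was -0.38 (adjusted p = 0.135). Adjusted p-values of the 15 genes ran from 0.00411 to 0.0193. Smim3 lost the call without 1A, without 1B, without 2A and without 2B, at adjusted p from 0.0548 to 0.0694. Map2 lost it without 1B and without 2B, and Plxnd1 lost it without 1B and without 2A. Without array 1C, Map2 and Plxnd1 lost the call.

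**Figure D1:**
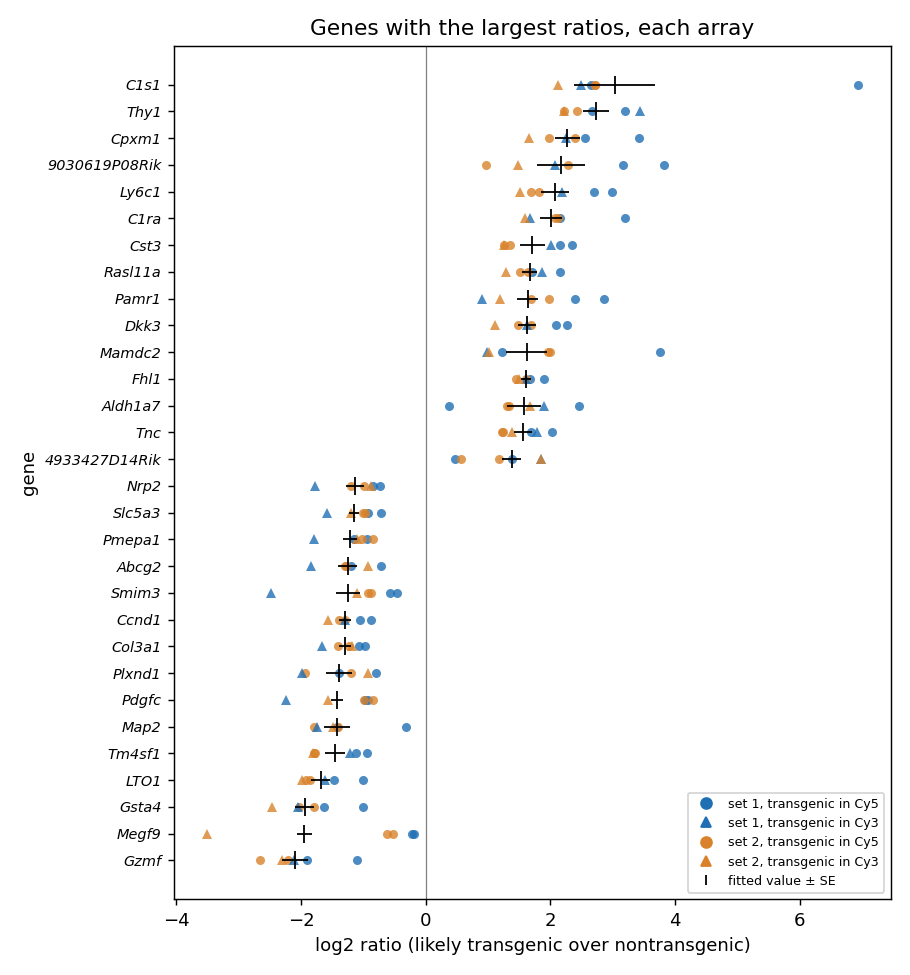
Log2 ratios (horizontal axis, likely transgenic over nontransgenic) of the 30 genes with the largest ratios past the threshold (vertical axis). Each point is 1 array, circles with transgenic RNA in Cy5 and triangles with it in Cy3, blue for set 1 and orange for set 2; black marks are the fitted value ± SE. Thy1 lies between 2.21 and 3.44 on the 6 arrays, C1s1 has 1 point at 6.93, and Megf9 has 1 point at -3.51 apart from the others.

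The count of changed genes depends on how the sets are treated. With the set as a random replicate block (estimated correlation 0.295), 197 rows passed, 121 higher and 76 lower, all of them among the 484, and C1s1, 9030619P08Rik, Mamdc2, Aldh1a7, Map2, Plxnd1 and Smim3 no longer passed, at adjusted p from 0.0652 to 0.158. Of the 52 genes called within the lists below, 27 kept the call with this block; among those that lost it are Grk5, Prkar2a, Atp2a2, Cdkn1b, Ctsb and Stat2, at adjusted p of 0.126, 0.127, 0.107, 0.104, 0.0529 and 0.109. With each set averaged to 1 value (n = 2), 0 of 6772 rows passed by limma and 728 had an unadjusted p under 0.05. Without the widely scattered array 1C, 188 rows passed, 159 of them among the 484; the other arrays left out in turn gave 168 to 251 rows, except array 2C, without which 1687 passed.

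Genes of the cell cycle had lower ratios in transgenic cells. Of 34 measured genes of this list, 6 fell and 0 rose (13 fell when adjusted over the list alone), and 29 of the 34 ratios were negative, with a median of -0.286. Besides Ccnd1, the genes that passed were Ccnd2, a further D-type cyclin (-0.68 ± 0.12), Mad2l1, a spindle checkpoint protein (-0.63 ± 0.10), and Mcm5, Mcm2 and Mcm4, subunits of the replicative helicase (-0.69 ± 0.11, -0.45 ± 0.08 and -0.41 ± 0.08). The list passed camera with the preset correlation (adjusted p = 3.63e-06) and fry (adjusted p = 0.0282). It did not pass with an estimated correlation (adjusted p = 0.542 with an estimated correlation of 0.202). With the set as a random block Ccnd1 alone of the 6 genes kept its call, and the other 5 had adjusted p from 0.0529 to 0.0938. In set 1 alone, added after seeing the data, the list as a whole had a median of -0.157 and did not pass camera.

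Cell cycle regulators of the growth arrest list went both ways. Of 13 measured genes, Gadd45b, a stress-induced growth arrest gene (0.97 ± 0.14), and Cdkn1b, the inhibitor p27 (0.91 ± 0.15), rose, and Cdkn1a, the inhibitor p21 (-0.72 ± 0.11), and Ccng1, a p53 target (-0.49 ± 0.07), fell. The list did not pass camera (adjusted p = 0.631, direction lower), with a median of -0.043 and a mean of 0.074.

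Matrix proteases and their inhibitors were the other list past the preset test (adjusted p = 0.0293), but not with an estimated correlation (adjusted p = 0.645 with an estimated correlation of 0.461). Of 15 measured genes, Cst3, Ctsb (0.45 ± 0.06) and Ctsl (0.91 ± 0.16) rose and Timp3 (-0.55 ± 0.10) fell. When adjusted over the list alone, 6 rose and 1 fell. The separate probes of Ctsb, tested alone, gave 0.71 ± 0.135 (adjusted p = 0.0364) and 0.18 ± 0.10 (adjusted p = 0.297). Cst3 encodes an inhibitor and Ctsb and Ctsl lysosomal cathepsins, and Timp3 encodes an inhibitor of matrix metalloproteinases. The call was also lost without array 1C (adjusted p = 0.241), on the 4 arrays with transgenic RNA in Cy5 (0.0541), with probes tested singly (0.0572) and with array weights (0.135), and fry gave an adjusted p of 0.105. It held in set 1 alone (median 0.383, 14 of 15 genes positive, adjusted p = 0.00756) and not in set 2 alone (median 0.146, 8 of 15 positive, adjusted p = 0.426).

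Extracellular matrix genes changed in both directions. Of 23 measured, 4 rose and 4 fell, and the median was -0.015. Tnc, Mfap5, a microfibril protein (0.81 ± 0.07), Thbs2, thrombospondin 2 (0.83 ± 0.11), and Lox, the enzyme that crosslinks collagen and elastin (0.62 ± 0.09), rose. Fn1, fibronectin (-0.83 ± 0.06), Col5a1 (-0.96 ± 0.07), Col3a1 and Col5a2 (-0.56 ± 0.07) fell. When adjusted over the list alone, 5 rose and 7 fell. The share of called genes exceeded that among the other named genes (Fisher's exact test, one-sided, adjusted p = 0.00387 over the 26 lists), while camera found no common shift (adjusted p = 0.878).

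**Figure D2:**
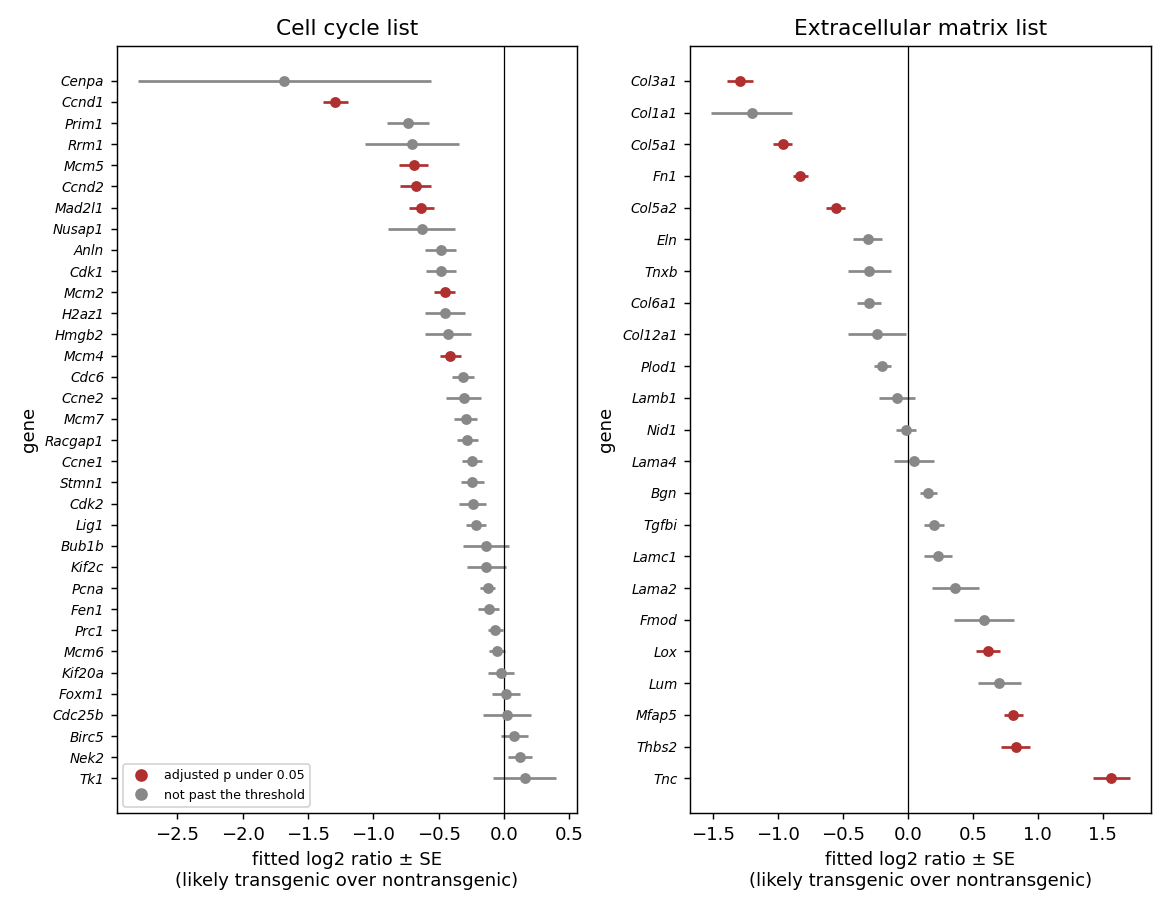
Fitted log2 ratios ± SE over 6 arrays (horizontal axes, likely transgenic over nontransgenic) of the measured genes (vertical axes) of the cell cycle and extracellular matrix lists. Red points passed the adjusted p of 0.05 and grey points did not. In the cell cycle list 29 of 34 genes lie below 0, and in the matrix list 4 genes passed on each side.

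Growth factor genes changed in both directions. Tgfbr3, the transforming growth factor beta co-receptor betaglycan, rose (1.34 ± 0.06, adjusted p = 0.00136), and its 3 probes gave 1.13, 1.26 and 1.62. Tgfbr1, the signalling receptor of that factor (-0.88 ± 0.07), Igf1 (-0.96 ± 0.08) and Igfbp3, an insulin-like growth factor binding protein (-1.11 ± 0.09), fell; of the 19 measured genes 1 rose and 4 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.242; fry adjusted p = 0.0366). Of 10 cytokine and chemokine genes, Tgfb2, encoding a ligand of these receptors, fell (-1.03 ± 0.09) and Cxcl12, a chemokine, rose (0.65 ± 0.07; 1.21 at one of its probes and 0.08 at the other); the list's adjusted p was 0.561.

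Genes of the receptor's own pathway did not pass camera as a list. Fry for changes in either direction gave the list of receptor, cyclic AMP and protein kinase A genes an adjusted p of 9e-05. Fry for a common direction gave it 0.127. The test for either direction does not single out this pathway. It gave lower adjusted p for epithelial markers (5.8e-07) and for skeletal and cardiac muscle markers (1.24e-06). Glycolysis (0.186) and ribosomal protein genes (0.211) did not pass it. Of 22 measured genes of receptor, cyclic AMP and protein kinase A signalling, Grk5, a kinase that phosphorylates activated receptors, rose (0.36 ± 0.07, adjusted p = 0.0392) and Prkar2a, a regulatory subunit of protein kinase A, fell (-0.50 ± 0.10, adjusted p = 0.04); the list's median was -0.087 (camera adjusted p = 0.227), and 1 rose and 3 fell when adjusted over the list alone. Of 14 genes known as targets of the cyclic AMP-responsive factor CREB, Gadd45b alone passed; the median was 0.145 (camera adjusted p = 0.227, fry adjusted p = 0.00455). Of 11 genes of contractile receptor signalling, Rgs3, a regulator of G protein signalling, rose (0.34 ± 0.07), and the median was 0.002 with a mean of -0.001 (adjusted p = 0.985, direction lower).

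Calcium-handling genes were led by Casq2, the calcium-storage protein calsequestrin 2, which fell (-0.996 ± 0.093, adjusted p = 0.00518). Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose (0.34 ± 0.07) and Atp2b4, a plasma membrane calcium pump, fell (-0.39 ± 0.08); the list of 21 genes did not pass camera (median -0.036, adjusted p = 0.586). Pln, phospholamban, the inhibitor of that reticular pump, did not pass as the mean of its 4 probes (-0.33 ± 0.10, adjusted p = 0.115, lower on 5 of 6 arrays). The probes disagreed. Tested alone, probe 807862 fell by 1.26 ± 0.09 (adjusted p = 0.00434, lower on 6 of 6 arrays), while probe 807663 gave -0.24 ± 0.31, probe 807869 gave 0.26 ± 0.20 and probe 871676 gave -0.06 ± 0.08, none of them past the threshold.

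**Figure D3:**
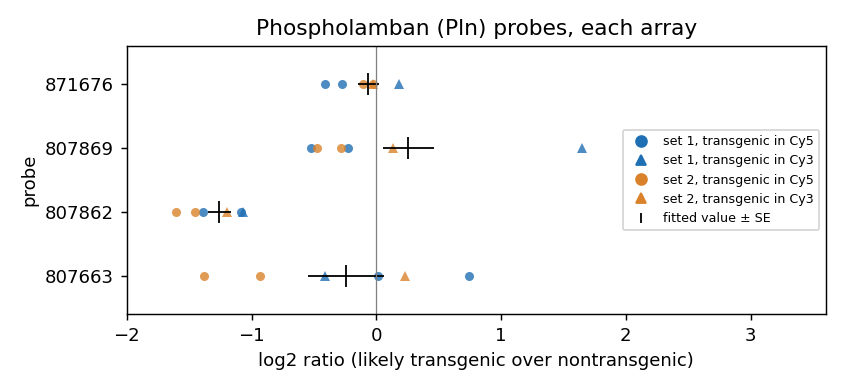
Log2 ratios (horizontal axis, likely transgenic over nontransgenic) of the 4 phospholamban probes (vertical axis) on each of the 6 arrays, with symbols by set and dye orientation as drawn in the key; black marks are the fitted value ± SE. Probe 807862 lies between -1.61 and -1.07 on every array, and the fitted values of the other 3 probes lie between -0.24 and 0.26.

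Smooth muscle and contractile genes did not pass camera as a list. Of 17 measured genes, Fhl1, Vcl, the adhesion protein vinculin (1.15 ± 0.14), and Cnn1, calponin 1 of smooth muscle (0.59 ± 0.105), rose and 0 fell, and the median was -0.020 with a mean of 0.172 (camera adjusted p = 0.511, direction higher; fry adjusted p = 0.0332); adjusted over the list alone, 3 rose and 1 fell. Among markers of other cell types that a tracheal explant could hold, Thy1 and Mfap5 rose of 9 fibroblast genes (median 0.149, adjusted p = 0.107, fry adjusted p = 0.0127), Col11a1 fell (-1.10 ± 0.09) of 6 cartilage genes (median -0.201, adjusted p = 0.152, fry adjusted p = 0.0154), L1cam (-0.45 ± 0.07) and Uchl1 (-0.46 ± 0.09) fell of 10 neural and Schwann cell genes (median -0.083, adjusted p = 0.195), Cdh1 rose (0.32 ± 0.06) of 11 epithelial genes (median -0.110, adjusted p = 0.586), and Mb rose (0.29 ± 0.06) of 8 skeletal and cardiac muscle genes (median 0.092, adjusted p = 0.24, fry adjusted p = 0.0358). The fibroblast list passed camera without array 1C (median 0.23, adjusted p = 0.0148), without 1B (0.045, adjusted p = 0.0454) and with set means (adjusted p = 0.0111). None of 15 macrophage and leukocyte genes (median 0.027, adjusted p = 0.985), 9 endothelial genes (median -0.103, adjusted p = 0.754) and 5 adipocyte genes (median 0.062, adjusted p = 0.64) passed. Adjusted over the list alone, 4 fibroblast genes rose and 1 fell, and 4 neural genes fell. In the same way Cdh1 rose and 1 other epithelial gene fell, and 1 endothelial gene rose and 2 fell.

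Lipid and interferon genes gave calls in 1 direction. With the set as a random block Idi1 and Gbp2 kept the call, and Sqle, Fads1, Ifitm2 and Stat2 lost it. Idi1 and Sqle, enzymes of cholesterol synthesis, and Fads1, a fatty acid desaturase, rose (0.66 ± 0.07, 0.91 ± 0.19 and 0.38 ± 0.08) among 15 genes of sterol and fatty acid synthesis (median 0.205, camera adjusted p = 0.107, fry adjusted p = 0.0303; 5 rose and 1 fell when adjusted over the list alone). Gbp2, Ifitm2 and Stat2, all interferon-inducible, rose (0.73 ± 0.09, 0.86 ± 0.17 and 0.42 ± 0.09) among 23 interferon response genes (median 0.169, camera adjusted p = 0.107, fry adjusted p = 0.0223). With 1 array left out the median ranged from 0.087 to 0.216 for the interferon list, from 0.128 to 0.275 for the sterol list and from -0.245 to -0.039 for the antioxidant list. Of 11 antioxidant genes, Gsta4 and Txnrd1, thioredoxin reductase 1 (-0.68 ± 0.09), fell (median -0.129, adjusted p = 0.242; 2 rose and 4 fell when adjusted over the list alone). Of 12 genes of protein folding in the endoplasmic reticulum, Sel1l rose (0.45 ± 0.095; median -0.175, adjusted p = 0.267, fry adjusted p = 0.0174; 2 rose when adjusted over the list alone). Among 20 oxidative phosphorylation genes (median 0.139, adjusted p = 0.195), 17 ribosomal protein genes (median 0.078, adjusted p = 0.586) and 8 glycolysis genes (median 0.041, adjusted p = 0.985), 0 passed.

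The dye comparison asked which probes gave different ratios when the dyes were exchanged. Suox, sulfite oxidase, was the 1 gene past the threshold (Cy5 over Cy3, 1.71 ± 0.07, adjusted p = 0.00216), and 1242 of 6807 rows had an unadjusted p under 0.05. Suox also counted among the 484 changed genes (-1.53 ± 0.07), but both calls came from a probe at the floor on the swapped arrays; with floor values missing it was at 0.17 (adjusted p = 0.208) and 0 genes passed for dye. Megf9 (1.56 ± 0.12) and Krt7, an epithelial keratin (-0.82 ± 0.08), followed at adjusted p = 0.116.

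The set comparison asked whether the transgenic ratio differed between sets 1 and 2. By limma 0 of 6807 rows passed, and 1616 (23.7%) had an unadjusted p under 0.05. The 5 genes with the smallest p, each at adjusted p = 0.0716, were Malat1, a nuclear long noncoding RNA (1.43 higher in set 2), Prkce, protein kinase C epsilon (1.31), Ppfibp1 (1.26), Wdr13 (4.29) and Il4 (1.89). For Prkce the ratio lay between -0.54 and -0.52 on the 3 arrays of set 1 and between 0.72 and 0.85 on the 3 of set 2. Of the 4 Malat1 probes 3 had values, and 1 of these carried its set difference: it gave -0.80 to -0.49 in set 1 and 2.71 to 3.39 in set 2.

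Agreement between arrays followed both set and dye. The mean Pearson correlation across probes was 0.639 for the 2 pairs of the same set and dyes, 0.379 for 5 pairs of different sets with the same dyes, 0.141 for 4 pairs of the same set with opposite dyes and 0.088 for 4 pairs of different sets with opposite dyes; probes are not independent replicates.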

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

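All tests in this part were chosen after the results they bear on had been seen. Among 134 named genes, 6 had 1 of the 4 arrays with transgenic RNA in Cy5 far from the other 3, and chance alone gives about 1 in 20. C1s1 read 6.93 on array 1A against 2.66 to 2.72, C1ra 3.20 on 1A against 2.08 to 2.15, and Grk5 0.55 on 1A against 0.28 to 0.29. Atp2a2 read 0.40 on array 1B against 0.60 to 0.64, Suox -0.04 on 1B against 0.22 to 0.26, and Lum 1.33 on array 2A against 0.29 to 0.43. Suox also had a fitted dye term (Cy5 over Cy3) of 1.71, from a probe at the floor on both swapped arrays. Its mean ratio was 0.17 with transgenic RNA in Cy5 and -3.24 with it in Cy3.

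The lower ratios of the cell cycle list are the first pattern weighed. A dye effect would turn the sign of the median between orientations if the swapped columns are already turned, and it was -0.216 with transgenic RNA in Cy5 (95% bootstrap interval over genes -0.26 to -0.158) and -0.397 with it in Cy3 (-0.573 to -0.246); as the turning is not stated in the labels, a dye effect stays open. The scattered array 1C was not needed: without it the median was -0.292 and the list passed the preset test at adjusted p = 9.84e-09. Whether set 2 carries the list stays open, since the median was -0.157 in set 1 and -0.364 in set 2 and set 1 alone did not pass (adjusted p = 0.0598). Set 1 leaned the same way as set 2, with a 95% bootstrap interval over genes of -0.308 to -0.076 and 25 of 33 genes negative. A slower-growing transgenic culture and an effect of the receptor both remain untested. The labels give 1 passage range for all cultures and no cell density.

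The rise of Thy1 with other fibroblast markers is the second. A larger share of fibroblasts in the transgenic cultures could raise Thy1, and it should then raise the other 8 markers of that list. Their median was 0.111 (95% bootstrap interval -0.023 to 0.812), with 6 of 8 above 0 and only Mfap5 past the threshold, and leaving out 1 array moved the median of the whole list from 0.045 to 0.274: Dpt was at 1.67 ± 0.46, Lum at 0.70 ± 0.17 and Pdgfra at -0.02 ± 0.14. Members that go both ways decide nothing, and cultured smooth muscle cells also express several of them, so a shift in cell share and a change within the cells cannot be told apart. The abundant collagens of fibroblasts were not higher, with Col3a1 at -1.29 ± 0.10 and Col1a1 at -1.21 ± 0.31, but smooth muscle cells make these too.

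The disagreement of the phospholamban probes is the third. With dye removed by the fit, the most precise other probe stood at -0.063 with a 95% interval of -0.26 to 0.14, above -0.63, which is 0.5 of the fall of probe 807862; this argues against a dye effect only if the swapped columns are already turned, so that explanation stays open. Noise at single arrays is argued against, since probe 807862 lay below each of the other 3 on 6 of 6 arrays, although it was singled out as the lowest. Weak signal at the other spots, or a transcript or sequence that only some probes read, may explain the difference and stays untested, because intensities and probe sequences were not used here. A real fall of phospholamban in transgenic cells remains open in the same way.

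The count of changed genes was set against the other ways to assign the exchanged dyes to 2 of the 6 arrays. The real assignment called 484 rows and the highest of the other 14 called 0, but 1 of 15 is above 0.05, so the splits are too few for a share under 0.05. For the set comparison the real count of limma calls was 0, which 10 of 10 splits into 3 and 3 reach whatever the data (the highest other gave 4), so this count says nothing about chance. At an unadjusted p under 0.05 the real split had 1616 rows and the highest other 567, and 10 splits are too few for a share under 0.05.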

How the results depend on the processing

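Alternatives with set 1 or set 2 alone, with floor values missing and with sparsely measured probes dropped were chosen after seeing the data; the others were fixed before the data were examined. The fit as designed called 484 rows. The count was 1058 on the 4 arrays with transgenic RNA in Cy5 (382 of them among the 484), 197 with the set as a random replicate block, 1168 with it as a fixed replicate block, 0 with set means, 194 with array weights, 1056 in set 1 alone (238 among the 484), 907 in set 2 alone, 168 to 1687 with 1 array left out, 95 and 1021 at adjusted thresholds of 0.01 and 0.10, and 233 with at least 1.5-fold; the cause was not tested. Without 2C, array 1C is the only swap and is assumed to vary like the others; dye calls then number 988. The fits of each set alone and the fit without 1C also hold only 1 swapped array. Calls and lost calls there rest on the same assumption. Centring moved almost nothing, as the values were already centred. The number of lists called, 2 in the fit as designed, was 1 on the 4 Cy5 arrays, with probes tested singly, with array weights (each without the protease list) and in set 1 alone (without the cell cycle list), and 2 to 4 with 1 array left out; it was 3 in set 2 alone, where the interferon (adjusted p = 0.0345) and neural lists (0.0345) passed and the protease list did not, and 3 with set means, where the fibroblast list joined. Without 1B the interferon and fibroblast lists joined, and without 1C the fibroblast and neural lists passed and the protease list did not. Dye calls were 0 with single probes and with floor values missing and ranged from 1 to 988 with 1 array left out. Set calls were 3 after scaling and 1 with single probes, and 0 with 1 array left out. Pln passed at -0.59 on the 4 Cy5 arrays, at -0.33 with the fixed replicate block and at -0.50 in set 2 alone; its most contrary probe was at 0.26. Of 656 values of the 30 largest genes under these settings, 571 kept direction and call and 85 lost the call. None changed sign. These genes were chosen for the same sign on every array measured, so their sign could hardly change under these settings. The unchanged sign is therefore no separate test of their direction.

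Suox turned to 0.17 on the 4 Cy5 arrays, with single probes, with floor values missing and with sparse probes dropped, where its floor values no longer enter. The other sign changes, their cause not tested, were in genes and lists that had not passed in the fit as designed; Krt7 on the 4 Cy5 arrays, Prkce in set 1 alone and Cebpa and Il4 in set 2 alone passed with the turned sign. Krt7 was at -0.09 without the dye term. On the 4 Cy5 arrays Krt7 was at -0.63, Aldoc at -0.04, Adgre1 at 0.05, the macrophage list at -0.043 and the smooth muscle list at 0.039; the macrophage list was at 0 without the dye term. The contractile receptor list was at -0.002 after centring, -0.012 after scaling and -0.036 with array weights. Cdh5 was at 0.13 with its most contrary probe. With array weights Cd36 was at 0.05, Il4 at 0.19, the glycolysis list at -0.006, the macrophage list at -0.008 and the smooth muscle list at 0.005. In set 1 alone Myh4 was at 0.04, Prkce at -0.53, the calcium list at 0.037, the matrix list at 0.077 and the endothelial list at 0.109. In set 2 alone Cxcl9 was at -0.02, Gnaq at 0.04, Cebpa at 0.36, Cd36 at 0.22, Rpl3 at -0.03, Ppfibp1 at 0.34, Il4 at 0.73, the macrophage list at -0.014, the oxidative phosphorylation list at -0.045, the ribosomal list at -0.159 and the smooth muscle list at 0.014. With 1 array left out, Il4 ranged from -0.64 to 0.24, Cd36 from -0.22 to 0.06, Ppfibp1 from -0.64 to 0.03, Prkce from -0.20 to 0.46, and the lists of contractile receptors from -0.027 to 0.035, growth arrest from -0.106 to 0.014, endothelium from -0.18 to 0.008, smooth muscle from -0.026 to 0.073, matrix from -0.075 to 0.001, macrophages from -0.039 to 0.047, calcium from -0.068 to 0.026 and neural cells from -0.264 to 0.02. Signal over background is unknown here and limits what a ratio near 0 shows.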

Other observations

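All tests and genes in this part were chosen after their values had been seen. Genes of lysosomal proteins recurred among the higher genes. Of 27 measured genes of a lysosome list, 9 rose and 1 fell. Asah1, acid ceramidase (0.90 ± 0.12), Gla, alpha-galactosidase A (0.56 ± 0.06), Tpp1, a lysosomal peptidase (0.55 ± 0.07), Lipa, acid lipase (0.52 ± 0.07), and Lamp1, a lysosomal membrane protein (0.62 ± 0.11), were among those that rose, and Ctsc, cathepsin C (-0.75 ± 0.11), fell. With the set as a random block 4 of these 10 kept the call, and Lamp1 and Ctsc did not (adjusted p = 0.0602 and 0.0657). The median was 0.258, with 0.437 in set 1 and 0.097 in set 2. The hypothesis that lysosomal genes as a group may be higher in transgenic cells had p = 0.000223 with camera's preset correlation but p = 0.0611 with an estimated one, and the list was written after called members were known, so it stays undecided.

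Genes of fatty acid oxidation and peroxisomes gave a similar picture. Of 13 measured, 5 rose and 0 fell: Cpt1a, the enzyme that admits long-chain fatty acids to mitochondria (0.92 ± 0.11), Phyh (0.86 ± 0.14), Ech1 (0.82 ± 0.15), Pex16, a peroxisome assembly factor (0.63 ± 0.09), and Acadsb (0.46 ± 0.06). With the set as a random block 3 of the 5 kept the call, and Phyh and Ech1 did not (adjusted p = 0.0942 and 0.0551). The median was 0.302, with 0.462 in set 1 and 0.147 in set 2. That these genes may be higher as a group had p = 0.0012 with the preset and p = 0.05 with an estimated correlation, at the threshold and on a list written in the same way.

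The lowest fitted ratio of all belongs to a probe without a gene name here, 571759, at -4.11 ± 0.19 (adjusted p = 0.00136), with -4.44 to -3.17 on the 6 arrays. Eif2s3y, a gene of the mouse Y chromosome, had ratios of -0.91, -0.94 and -1.26 on the 3 arrays of set 1 and -0.02, -0.11 and -0.14 on the 3 arrays of set 2, a set difference of 0.94 (unadjusted p = 0.000331, adjusted p = 0.0716). Whether the transgenic and nontransgenic cells of set 1 differed in sex was not tested. In set 1 such a difference could not be told apart from the transgene. The calls above include set 1 and carry this limit. Wdr13 ranged from -5.85 to -4.42 in set 1 and from -1.18 to 0.07 in set 2.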
